A study of Mus musculus with 2 samples.

How the data were processed

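Chromatin carrying H3K27me3 was immunoprecipitated from lungs of mouse embryos at embryonic day 16.5 and sequenced, in 2 biological replicates of pooled male and female embryos, each with 2 technical replicates per the labels. The authors deposited 4 peak lists in the narrowPeak format on the mouse build mm10, per the file notes: 1 per biological replicate, 1 from both replicates pooled, and 1 of replicated peaks derived from the pooled list and both replicate lists. Per the file notes, the list of replicate 1 was derived from 1 alignment file and 2 auxiliary files, and that of replicate 2 from 1 alignment file and 1 auxiliary file; whether the auxiliary files were controls is not stated. The aligner, the peak caller, their versions and thresholds are not given in the sources used here.

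Each peak had a deposited signal value, which the authors gave as an enrichment ratio (a fold in this format), without a statement of what it was divided by. Each also had a deposited −log10 p and −log10 q from the peak caller, and a deposited score that was not used in any test. Values were used as deposited, and signal values were compared within a list or between overlapping peaks only. The files gave no reads or totals, so the depth is unknown, and no interval that needs read counts was computed. A narrowPeak list splits a broad mark such as H3K27me3 into many short peaks, so counts of peaks depend on depth and on the caller, and covered length was given beside them.

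The replicated list was the main list. All of its 21324 peaks were identical to peaks of the pooled list of 30194 peaks, 95.4% overlapped a peak of replicate 1, 44.7% one of replicate 2, 42.6% both and 2.49% neither. The median −log10 q was 2.65 in replicate 1, 1.01 in replicate 2 and 2.69 in the replicated list. The values of the replicates' own lists served as the replicate error (mean ± SD, n = 2). No contrast was tested across the 2 replicates, and every p compares genes, peaks or positions within these samples. Genes and peaks are not biological replicates.

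Genes came from the GENCODE M21 annotation and sequence from the GRCm38.p6 assembly, both of the build of the files, on chromosomes 1 to 19 and X, which held all peaks. Coordinates are printed 1-based. The TSS was the 5′ end of a protein-coding gene. A promoter was the TSS ± 1 kb and was called marked when a replicated peak overlapped it by at least 1 bp. Covered length per gene was measured in the TSS ± 5 kb. CpG observed/expected was taken in the TSS ± 500 bp. For the genomic distribution each base was assigned once, in the order promoter, 5′ untranslated region, coding exon, 3′ untranslated region, other exon, intron and intergenic.

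Overlaps and distributions were compared with 100 seeded circular shifts of the peaks within each chromosome (permutation test). Gene lists were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 17 lists at a threshold of 0.05, and with 10000 random lists matched on the decile of CpG observed/expected (two-sided permutation test, adjusted likewise). Chromosome X was compared with autosomes by Fisher's exact test on promoters. Domains were replicated peaks joined when within 3 kb, and the widest were taken as those with the most covered bases. Exact intervals of shares are Clopper-Pearson at 95%, and a share of 0 was given with the limit of 3 counts.

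The lists, tests and alternatives were fixed before the data were examined. The lists were Hox clusters, neural transcription factors, transcription factors of other endodermal organs, transcription factors of muscle, heart, limb, kidney and early mesoderm, secreted developmental ligands, lung epithelium, lung mesenchyme, endothelium, blood cells, pulmonary neuroendocrine cells, differentiated cells of other organs, imprinted genes, Polycomb subunits and antagonists, cell cycle inhibitors, housekeeping genes, germline genes and olfactory receptors. Named genes followed a fixed rule: the 20 genes with the most covered bases within 5 kb of the TSS; in each list up to 4 marked members with the most covered bases and up to 4 unmarked members in alphabetical order; the genes of the 10 widest domains; the genes nearest the 5 peaks of highest signal; and the 5 list genes of highest signal marked in only 1 replicate. Xist, the members of gene families and genes named to complete a count of 5 or fewer were chosen after their values were seen.

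Alternatives were a −log10 q of at least 5, each replicate's own list (leaving out the other replicate), the pooled list, replicated peaks overlapping both replicates, promoters of 2.5 kb or 500 bp either side, any annotated transcript start, at least 200 bp of the promoter covered, an overlap of at least 50% of the smaller peak, equal numbers of top peaks, peaks within 1 kb merged, promoters of CpG observed/expected of at least 0.6 only, CpG content within 250 bp of the TSS, and merging distances of 1 kb and 10 kb. A −log10 q of at least 2 was added after the data were seen.

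The steps were tested on simulated data with the 21755 genes. A simulated unrelated peak list, itself made by a circular shift, shared 1.54% of peaks, against 1.57% after shifts, which checks the computation only. The list test recovered 96% of changed lists at a false call rate of 0.625%, with unchanged genes marked independently at a common rate. Changed lists were simulated with a large excess of marked genes, so the 96% does not carry over to lists with a smaller excess. The simulation held no clustering of marks and no dependence on CpG content, so the false call rate does not carry over to lists with either. Covered lengths showed 0 mismatches with a direct count. Analyses used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9.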

Results

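Trimethylation of histone H3 at lysine 27 (H3K27me3), the modification laid down by Polycomb repressive complex 2, was profiled by chromatin immunoprecipitation and sequencing in lung tissue of mouse embryos at embryonic day 16.5. The series held 1 group of 2 biological replicates, each made from lungs pooled from male and female embryos. Replicate 2 came from 41 embryos, and the labels gave no number for replicate 1. The data were 4 peak lists in mm10 coordinates, namely the list of each replicate, a list called on both replicates pooled, and a list of replicated peaks. There was no second condition, so the comparisons were between the replicates, between groups of genes and between parts of the genome. The files held no read counts, so the depth of each sample was unknown.

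Replicate 1 had far more H3K27me3 peaks than replicate 2, and most peaks of replicate 2 overlapped one of replicate 1. Promoters of Six3 and Neurog1, which encode regulators of forebrain and sensory neuron development, were covered over all 2001 bp of the window (1 kb either side of the transcription start site, TSS) in both replicates. Otx1 and Gsc, which encode homeodomain factors of the early head, had 1780 bp and 1619 bp of the same window covered in replicate 1 and 0 bp in replicate 2. Otx1 nevertheless had 4722 bp covered within 5 kb of its TSS in replicate 2, against 9367 bp in replicate 1. Replicate 1 held 44426 peaks over 24.1 Mb and replicate 2 held 18480 peaks over 7.67 Mb, a ratio of 2.40 in number and 3.14 in covered length. Of the peaks of replicate 2, 89.1% overlapped a peak of replicate 1 by at least 1 bp, against a mean of 1.53% after circular shifts of the peaks along each chromosome. Of the peaks of replicate 1, 20.9% overlapped a peak of replicate 2, against 0.559% after shifts. Both shares exceeded all 100 shifts (one-sided permutation test, p = 0.0099, the smallest that 100 shifts can give). The share of replicate 1 peaks that were shared depended on the peaks taken, at 41.8% for equal numbers of top peaks by p value, 8.85% at −log10 q of at least 2 and 3.96% at −log10 q of at least 5. At these thresholds replicate 2 kept 3976 and 400 peaks against 27999 and 9275 in replicate 1, which limits that share, and 99.5% and 100% of the peaks of replicate 2 were shared.

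Across the 16459 peaks of replicate 2 with a partner in replicate 1, the signal value had a Spearman rho of 0.369 and, on the log2 scale, a Pearson r of 0.379. The median signal of these peaks was 6.20 in the replicate 1 partner and 3.62 in replicate 2, while over all peaks of each list it was 3.47 and 3.50. Only 9294 peaks of replicate 1 had a partner, so many pairs share a replicate 1 peak. These correlations ran across peaks, and peaks, like genes below, are not biological replicates. At −log10 q of at least 5 in both replicates only 400 pairs remained, with a rho of 0.148. Among the 459 genes of the fixed gene lists other than olfactory receptors, 211 promoters were marked in both replicates, 47 in replicate 1 alone and 1 in replicate 2 alone. The 5 discordant genes with the highest signal were Otx1, Gsc, Pcgf1 (a subunit of a variant Polycomb complex), Calca (the calcitonin gene) and Nr5a2 (a nuclear receptor of liver and pancreas). All were marked in replicate 1 alone, with 643 bp of the promoter window covered at Pcgf1, 1456 bp at Calca and 212 bp at Nr5a2.

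The replicated peaks gathered at promoters and exons and were sparse between genes. Promoters held 19.4% of the 17.3 Mb covered by the 21324 replicated peaks, 11.5 times the share after circular shifts. The 5′ untranslated regions were 10.1 times, coding exons 4.07 times, 3′ untranslated regions 2.25 times and other exons 2.23 times over the shifted peaks. Introns held 38.2% of the covered length (0.918 of the shifted share) and intergenic sequence 28.7% (0.551 of the shifted share). The promoter share was 18.7% ± 3.15 (mean ± SD, n = 2) in the lists of the replicates. All 7 shares lay outside those of the 100 shifts (two-sided permutation test, p = 0.0198, the smallest that 100 shifts can give). With promoters taken as 2.5 kb either side of the TSS their share was 39.5%.

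H3K27me3 marked the promoters of 2903 of 21755 protein-coding genes (13.3%, exact 95% binomial interval 12.9% to 13.8%, which covers counting error over genes only). The replicates marked 3752 and 2112 promoters, a mean of 2932 ± 1160 (SD, n = 2). Of the promoters marked in replicate 2, 98.4% were also marked in replicate 1, so 2079 were shared, where independent lists of these sizes would share 364. Only 33 promoters were marked in replicate 2 alone and 1673 in replicate 1 alone. Of the 2903 promoters marked by replicated peaks, 2870 were marked in the list of replicate 1 and 2050 in the lists of both replicates. At −log10 q of at least 5 the count of marked promoters was 1545.

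Developmental transcription factors were among the most heavily covered genes. Within 5 kb of the TSS (a window of 10001 bp), replicated peaks covered the whole window at Six3 (chromosome 17, TSS 85613608), Olig2 (chromosome 16, TSS 91225457), Gata2 (chromosome 6, TSS 88193891), Pax7 (chromosome 4, TSS 139833528) and Pax6 (chromosome 2, TSS 105668900). These factors act in the forebrain, oligodendrocytes, blood, muscle and the eye, in that order. The next in rank were Neurog1 (9959 bp), Insl3 (9950 bp, a hormone of the testis), Hmx1 (9937 bp), Tfap2c (9901 bp) and Hoxd11 (9890 bp). The rest of the first 20 were Neurod2, Hoxc9, Skor1, Lhx1, Hoxc5, Slc6a5 (a neuronal glycine transporter), Hoxc12, Onecut3, Barx1 and Cdx2, the last with 9790 bp. In replicate 2 the same windows were covered less, for example 8203 bp at Six3, 8612 bp at Olig2, 6302 bp at Barx1 and 6252 bp at Hoxc12.

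Every Hox gene and every neural transcription factor of the fixed lists was marked. The lists asked how often genes of other lineages and of the lung itself carried the mark, and each was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 17 lists. All 39 Hox genes were marked (exact test, adjusted p = 3.49e-34), as were all 42 neural transcription factors (adjusted p = 1.20e-36). In random lists matched on promoter CpG content the expected shares were 19.3% and 17.6%. Neighbouring Hox genes can share a promoter window, as Hoxd3 and Hoxd4 nearly do (TSS 74711927 and 74711929). The test counts such genes as independent, so its p overstates the evidence here and in any list with members side by side. Olig2, Pax6, Neurog1 and Neurod2 led the neural list by covered length. Replicate 1 marked all 39 Hox and all 42 neural genes, and replicate 2 marked 36 and 41 of them. At −log10 q of at least 5, 76.9% of the Hox genes and 97.6% of the neural genes were marked. With replicated peaks overlapping both replicates the shares were 89.7% and 100%.

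Transcription factors of other organs were also marked more often than other genes. Among those of other endodermal organs, 20 of 25 were marked (exact test, adjusted p = 2.32e-13), led by Barx1 of the stomach, Cdx2 of the intestine, Foxe1 of the thyroid and Onecut1 of the liver. Hnf1a, Hnf4a, Foxn1 and Gcm2 were not marked, although Gcm2 had 196 bp of its promoter covered in replicate 1. Among factors of muscle, heart, limb, kidney and early mesoderm, 32 of 39 were marked (exact test, adjusted p = 1.76e-21), led by Pax7, Hand1, Six2 and Msx1. The muscle factors Myf5 and Myf6 had no covered base within 5 kb of the TSS in the replicated list or that of either replicate, and neither had the mesoderm factor Msgn1. The mesoderm factor Meox1 had 165 bp of its promoter covered in replicate 1 only. Secreted developmental ligands were marked at 35 of 43 genes (exact test, adjusted p = 4.17e-23), with 9289 bp covered around Gdf7, 9268 bp around Wnt10a, 8608 bp around Wnt10b and 8437 bp around Fgf8. In replicate 2 the covered length was 6137 bp around Gdf7 and 3845 bp around Fgf8. Bmp5, Fgf1, Fgf4 and Fgf20 were among the 8 unmarked ligands. The median covered length of marked genes was 8900 bp in the endodermal list, 8777 bp in the mesodermal list and 5530 bp in the ligand list, all with replicated peaks.

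**Figure D1:**
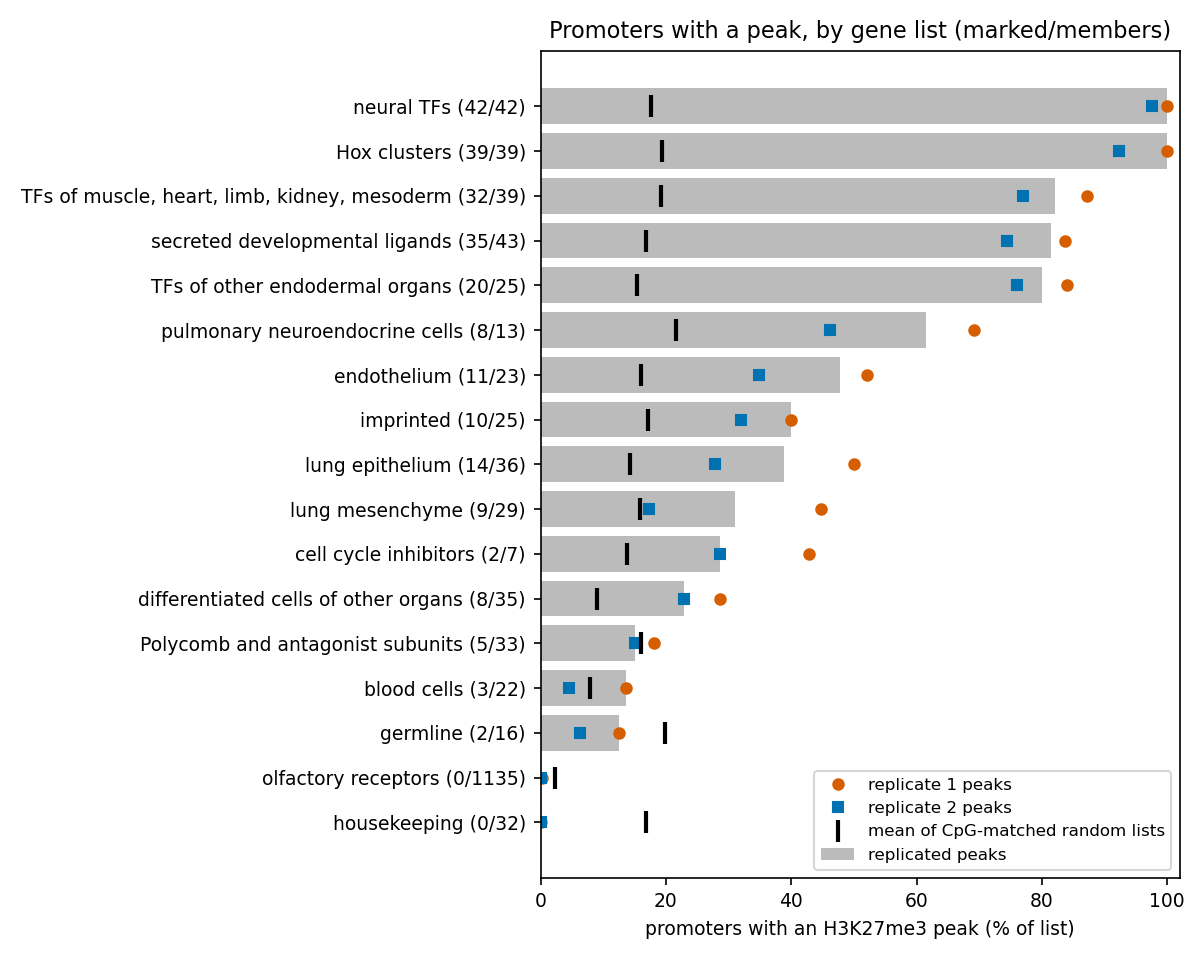
Share of promoters with an H3K27me3 peak (horizontal axis, % of the list) for each of 17 gene lists (vertical axis, with marked and total members; TFs, transcription factors); bars are replicated peaks, orange circles replicate 1, blue squares replicate 2, and black ticks the mean of 10000 random lists matched on promoter CpG content. Hox genes and neural transcription factors reach 100%, and housekeeping genes and olfactory receptors stay at 0.

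Promoters of lung epithelial, endothelial and neuroendocrine genes were marked more often than those of other protein-coding genes. These lists, like that of lung mesenchyme below, hold developmental transcription factors beside cell markers. The lists of transcription factors of other lineages were marked at 80% to 100% of genes. The tests did not separate factors from markers, so the shares are not a trait of lung cell markers as such. Lung epithelial genes were marked at 14 of 36 promoters (exact test, adjusted p = 2.2e-04), including Aqp5 (9012 bp covered, a water channel of alveolar type I cells), Sox2 (8570 bp, a factor of airway progenitors), Foxa1 (7356 bp) and Foxa2 (7350 bp). In replicate 2 the covered lengths were 6002 bp at Aqp5, 5407 bp at Sox2, 3060 bp at Foxa1 and 3341 bp at Foxa2. Ager and Cldn18, both of alveolar epithelium, had no covered base within 5 kb, while Bmp4 and Cebpa had 419 bp and 180 bp of the promoter covered in replicate 1 alone. Endothelial genes were marked at 11 of 23 promoters (exact test, adjusted p = 1.46e-04), led by the factors Sox7 (7843 bp) and Sox17 (6620 bp), the VEGF receptor Flt1 (7067 bp) and Sox18 (5312 bp). In replicate 2 the order differed, with 4104 bp at Sox17, 3897 bp at Sox18, 3889 bp at Flt1 and 2789 bp at Sox7. The vascular genes Cdh5, Egfl7, Emcn and Eng had no covered base. Genes of pulmonary neuroendocrine cells, a rare airway cell type, were marked at 8 of 13 promoters (exact test, adjusted p = 1.46e-04), with 8944 bp covered at Insm1, 8282 bp at Gfi1, 7726 bp at Ascl1 and 3686 bp at Uchl1, and none at Ddc, Scg2 and Scg5. In replicate 2 these lengths were 7380 bp at Insm1, 3841 bp at Gfi1, 4373 bp at Ascl1 and 1470 bp at Uchl1. Grp, another gene of this list, had 1184 bp of its promoter covered in replicate 1 and none in the replicated list.

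Lung mesenchymal genes were marked at 9 of 29 promoters (exact test, adjusted p = 0.0167), including Foxf1 (6718 bp), Pdgfra (4726 bp), Twist2 (4542 bp) and Tbx4 (4097 bp). In replicate 2 the covered lengths were 3072 bp at Foxf1, 1927 bp at Pdgfra, 1936 bp at Twist2 and 948 bp at Tbx4. Acta2, Col3a1 and Dcn, of smooth muscle and fibroblasts, had no covered base, and Col1a2 had 367 bp in replicate 1 alone. This list did not pass against CpG-matched random lists (two-sided permutation test, adjusted p = 0.0651), and with the peaks of replicate 2 alone 17.2% of it was marked (exact test, adjusted p = 0.238). All of these lung lists are averages over a mixed tissue, and the peaks do not show in which cells a promoter carried the mark.

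Blood cell genes were marked at 3 of 22 promoters (exact test, adjusted p = 1), namely Tal1, Ikzf1 and Klf1, while Adgre1, Cd19, Cd3e and Cd52 had no covered base. In replicate 2 only Ikzf1 was marked (4.55% of the list), and the promoters of Tal1 and Klf1 had 0 bp covered. Genes of differentiated cells of other organs were marked at 8 of 35 promoters (exact test, adjusted p = 0.168). The markers with the most covered length in this list were Nphs1 of the kidney (8414 bp), Slc17a7 of neurons (6419 bp), Acta1 of muscle (5369 bp) and Lor of the epidermis (3185 bp). In replicate 2 they had 3948 bp, 4030 bp, 2571 bp and 1112 bp covered, in that order. The liver genes Afp, Alb, Apoa1 and Apob had none. Against CpG-matched random lists, with an expected share of 8.99%, the adjusted p of this list was 0.0218 (two-sided permutation test), and with the peaks of replicate 2 alone the Fisher's exact test gave an adjusted p of 0.0261.

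Imprinted genes were marked at 10 of 25 promoters (exact test, adjusted p = 0.00144), led by Dio3 (8372 bp), Rasgrf1 (6573 bp), Grb10 (5511 bp) and Ascl2 (5013 bp), with no covered base at Igf2r, Impact, Magel2 and Mest. In replicate 2 the covered lengths were 7223 bp at Dio3, 3597 bp at Rasgrf1, 1937 bp at Grb10 and 1473 bp at Ascl2, and the promoter of Grb10 had 0 bp covered. Among promoters of CpG observed/expected of at least 0.6 the adjusted p of this list was 0.154. Polycomb subunits and their antagonists were marked at 5 of 33 promoters (exact test, adjusted p = 0.902), among them Epop, Cbx8, Pcgf1 and Pcgf5, while Aebp2, Asxl1 and Bap1 had no covered base and Bmi1 had none in the promoter window. Cell cycle inhibitors were marked at 2 of 7 promoters (exact test, adjusted p = 0.288), which were Cdkn2a (8180 bp covered) and its neighbour Cdkn2b (4944 bp), with 5032 bp and 3193 bp in replicate 2. Cdkn1b and Cdkn1c had no covered base, and Cdkn1a had 197 bp of the promoter covered in replicate 1 alone. Germline genes were marked at 2 of 16 promoters (exact test, adjusted p = 1), Stag3 with 269 bp and Dmc1 with 188 bp. In replicate 2 only Stag3 was marked (6.25% of the list), and Dmc1 had 0 bp covered.

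No housekeeping promoter of 32 was marked in any of the replicate or replicated lists, Actb, B2m, Chmp2a and Cox4i1 included, which allows a share of up to 9.38% (exact test, adjusted p = 0.0243). This call was lost with the peaks of replicate 2 alone (exact test, adjusted p = 0.0978) and at −log10 q of at least 5 (adjusted p = 0.203). None of 1135 olfactory receptor promoters was marked (exact test, adjusted p = 8.82e-72), which allows a share of up to 0.264%. Replicate 1 marked 3 of them. Receptor genes that lie side by side are not independent, so this p has the same limit as that of the Hox genes. The CpG-matched expectation was 16.9% for housekeeping genes and 2.37% for olfactory receptors.

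Promoters of intermediate CpG content were marked most often. The share of marked promoters rose from 0.919% in the lowest decile of CpG observed/expected to 26.9% in the fifth decile (0.406 to 0.558) and 25.4% in the sixth. It then fell to 10.9% in the highest decile. The fifth decile was at 34.2% in replicate 1 and 18.8% in replicate 2, and the highest at 13.2% and 8.23%. Spearman's rho between CpG content and marking across genes was 0.136, a description of a relation that was not monotonic.

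**Figure D2:**
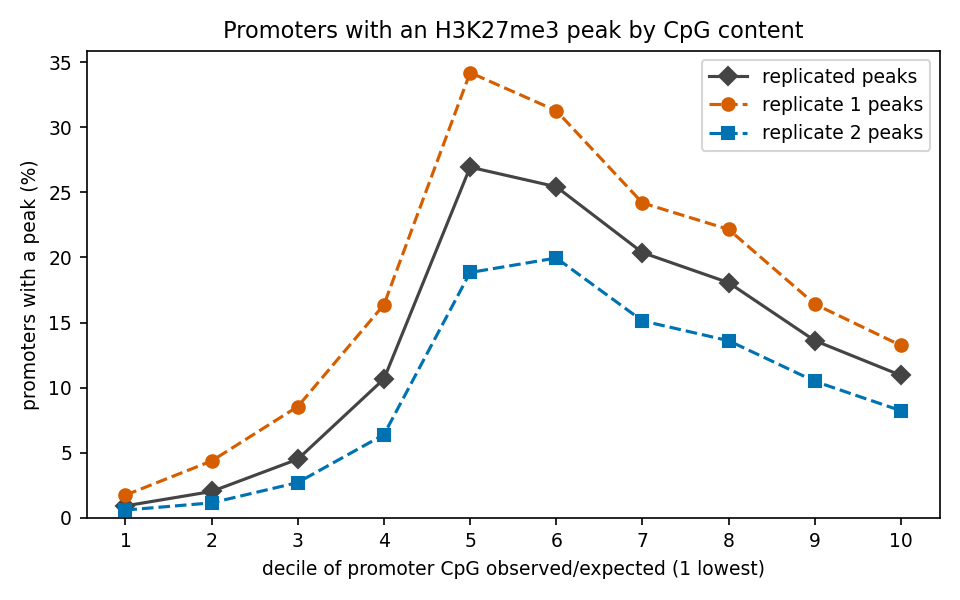
Share of promoters with an H3K27me3 peak (vertical axis, %) by decile of promoter CpG observed/expected (horizontal axis, lowest first); grey diamonds are replicated peaks, orange circles replicate 1 and blue squares replicate 2. The replicated list peaks at 26.9% in the fifth decile and falls to 10.9% in the highest.

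Domains at the Hox clusters ranked first in the genome by covered H3K27me3 bases. The ranks given here are by covered bases, and by width the Hoxa domain (151 kb) exceeded the Hoxd domain (127 kb). When replicated peaks within 3 kb were joined, 7121 domains resulted, and the 287 with over 10 kb of covered sequence held 32.5% of all covered bases. The first in rank spanned Hoxc4 to Hoxc13 (chromosome 15, 102897683 to 103071840), with 148 kb covered. The Hoxd cluster with Evx2 followed (chromosome 2, 74643408 to 74770796, 115 kb covered), then the Hoxa cluster (chromosome 6, 52146630 to 52297646, 99.0 kb) and Hoxb3 to Hoxb9 (chromosome 11, 96247091 to 96346509, 65.2 kb). The 6 other domains of the first 10 lay at Zic1 and Zic4 (59.5 kb), Pax3 (45.7 kb), Tfap2a (44.1 kb), Hand2 (42.8 kb), Hoxb13 with part of Ttll6 (42.5 kb) and Pax7 (41.4 kb). In replicate 1 these domains had between 42.7 kb at Hand2 and 150 kb at Hoxc covered, and in replicate 2 between 24.1 kb at Pax7 and 94.9 kb at Hoxc.

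Within the Hox clusters the coverage was not even. The annotated 5′ end lies over 5 kb from the start codon for 10 of the 39 Hox genes, by 46.6 kb for Hoxc5 and 40.7 kb for Hoxa3, so coverage was also measured within 5 kb of the start codon, a choice made after the data were seen. Around the start codons of paralog groups 1 to 5, peaks covered 4.43 kb ± 1.35 (SD over 5 genes) in Hoxa and 3.24 kb ± 2.44 (5 genes) in Hoxb, but 9.43 kb ± 0.365 (2 genes) in Hoxc and 9.04 kb ± 0.947 (3 genes) in Hoxd. Around those of groups 6 to 13 the means were 8.88 kb in Hoxa, 8.17 kb in Hoxb, 9.60 kb in Hoxc and 9.47 kb in Hoxd. These lengths depended on the replicate: for groups 1 to 5 they were 5.80 kb and 0.920 kb in Hoxa (replicates 1 and 2), 4.37 kb and 0.565 kb in Hoxb, 9.44 kb and 5.56 kb in Hoxc, and 9.21 kb and 6.73 kb in Hoxd. For groups 6 to 13 replicate 2 gave 5.34 kb in Hoxa, 4.53 kb in Hoxb, 7.16 kb in Hoxc and 7.46 kb in Hoxd. Neighbouring genes share much of their windows, so these genes are not independent.

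**Figure D3:**
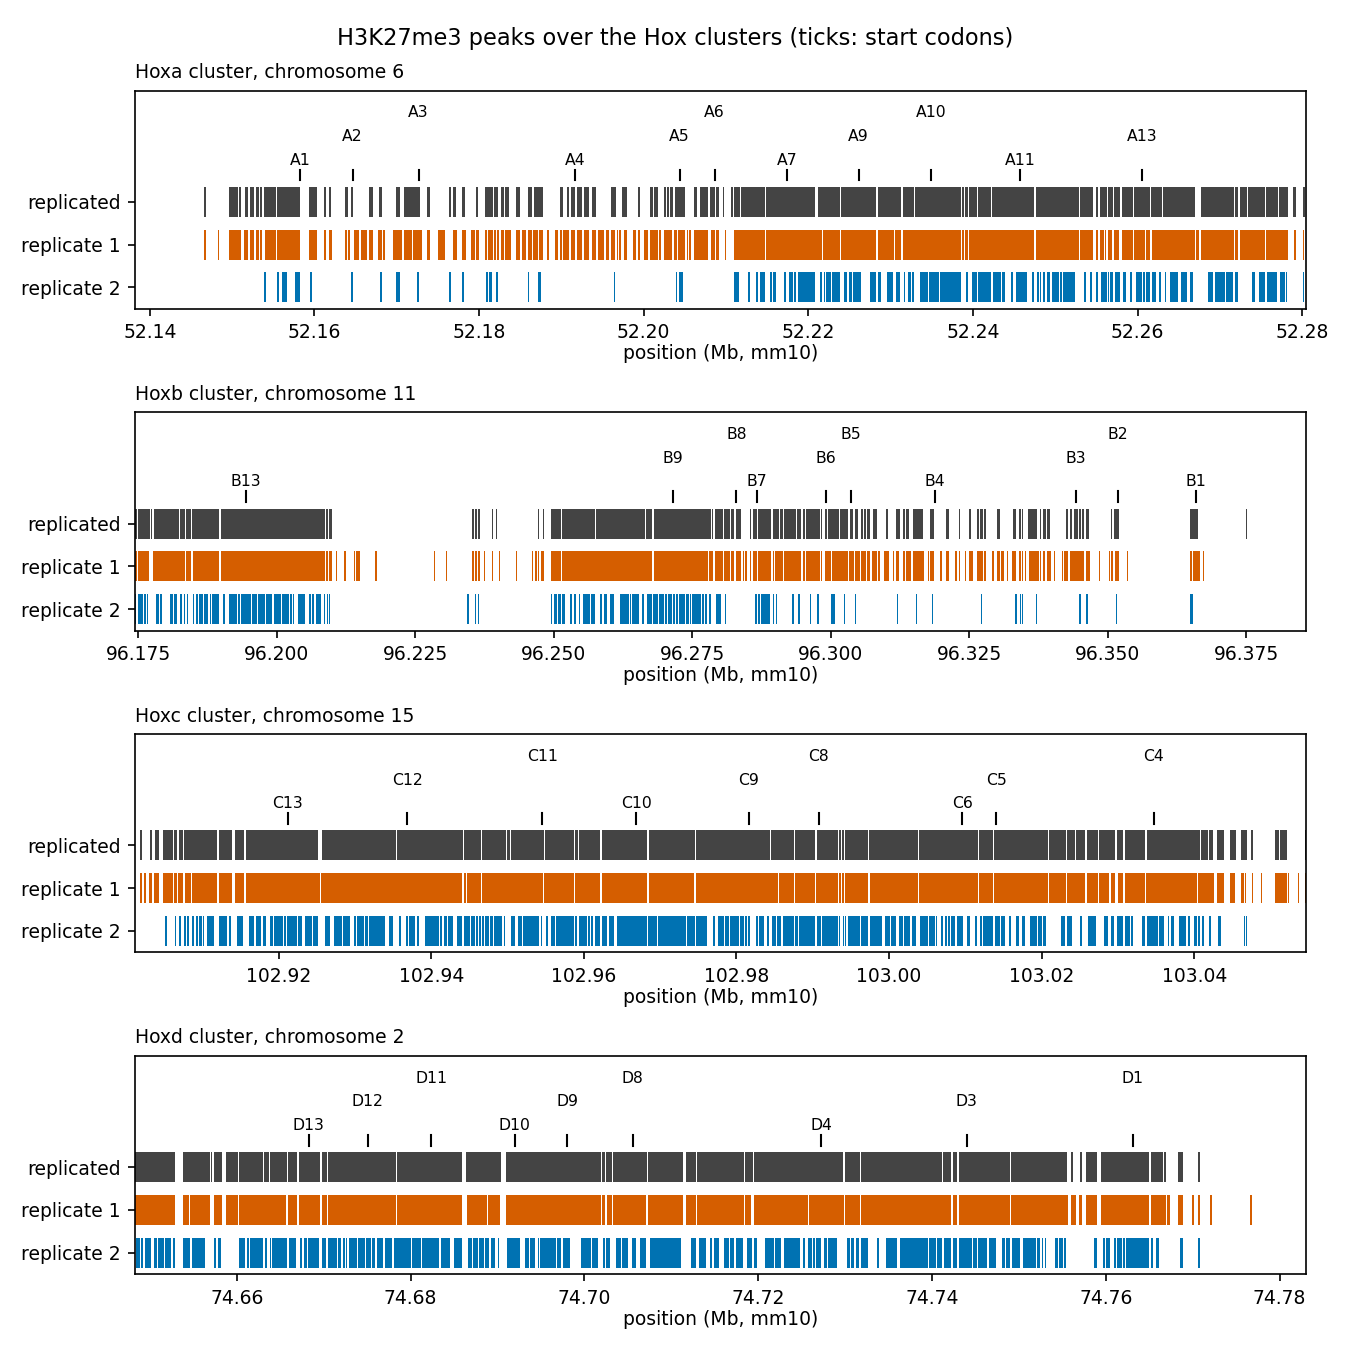
Maps of H3K27me3 peaks over the 4 Hox clusters (horizontal axis, mm10 position in Mb); each panel has 1 row of bars for the replicated peaks (grey), replicate 1 (orange) and replicate 2 (blue), and ticks mark start codons. Peaks are sparse around the start codons of groups 1 to 5 in Hoxa (mean 4.43 kb covered) and Hoxb (3.24 kb) and denser in Hoxc (9.43 kb) and Hoxd (9.04 kb) in the replicated list, with less coverage in replicate 2 in every cluster.

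Of the 5 replicated peaks of highest signal, the first, with a signal of 14.5, covered the TSS of Grik3, a kainate receptor subunit (chromosome 4, 125484206 to 125494201). The next lay 54 bp from the TSS of Islr and over its neighbour Islr2 (chromosome 9, 58195051 to 58204252, signal 14.4). Those at Adra2c, an adrenergic receptor (chromosome 5, 35275719 to 35282735, signal 14.1), and Fam43b (chromosome 4, 138392964 to 138397645, signal 13.5) covered the TSS. The fifth overlapped Vgf, a neuropeptide precursor (chromosome 5, 137030313 to 137032581, signal 12.7), 3.92 kb from its TSS. Signal values of overlapping peaks were higher in replicate 1 than in replicate 2 at Grik3 (18.97 against 7.998), Islr (17.3 against 7.30), Fam43b (17.3 against 8.28) and Vgf (15.7 against 7.71), and lower only at Adra2c (9.79 against 10.2).

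Genes on chromosome X had a called promoter peak less often than autosomal genes, while some parts of X were dense in small peaks. On X, 90 of 948 promoters were marked (9.49%), against 2813 of 20807 on autosomes (13.5%; Fisher's exact test, two-sided, p = 2.43e-04). The same direction held in replicate 1 (12.6% against 17.5%, exact p = 6.12e-05) and replicate 2 (7.70% against 9.80%, exact p = 0.0329). Single autosomes ranged from 10.1% to 20.1% in the replicated list, 14.0% to 24.3% in replicate 1 and 7.08% to 13.8% in replicate 2. X lay below every autosome in the replicated list and replicate 1, and within their range in replicate 2. The exact tests count genes and leave out this spread between chromosomes. Among promoters of CpG observed/expected of at least 0.6 the shares were 17.4% on X and 16.9% on autosomes (exact p = 0.799), and at −log10 q of at least 5 they were 1.16% and 7.37% (p = 2.50e-18). X had 3.33 kb covered per Mb against 6.80 kb on autosomes, within the range of single autosomes (2.97 to 12.2 kb). This was 4.77 kb against 9.45 kb in replicate 1 and 2.25 kb against 2.96 kb in replicate 2. X had 8.58 peaks per Mb against 8.06, within the range of single autosomes (3.75 to 13.6). Peak density was lower on X than on autosomes in replicate 1 (15.8 against 16.9 per Mb) and higher in replicate 2, where autosomes had 6.88 per Mb. Peaks on X were narrower, with a median width of 291 bp against 451 bp, and 9.74% of them lay at promoters against 22.3%.

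These small peaks formed bands along X, which were examined after the data were seen. Peaks of at most 500 bp lying over 5 kb from any protein-coding TSS averaged 6.16 per 1 Mb bin over 154 bins of X. They numbered 194 from 90 to 100 Mb, 234 from 100 to 110 Mb, 121 from 150 to 160 Mb and 229 from 160 to 170 Mb, and 0 from 110 to 130 Mb. In the same order the dense regions held 366, 440, 214 and 514 in replicate 1 and 210, 271, 119 and 331 in replicate 2. The densest bin of the replicated list, from 103 to 104 Mb, held 119 (173 in replicate 1, where the bin from 99 to 100 Mb held more, at 187). It contains Xist, the RNA gene that starts X inactivation (103460366 to 103483254), where no base was covered.

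**Figure D4:**
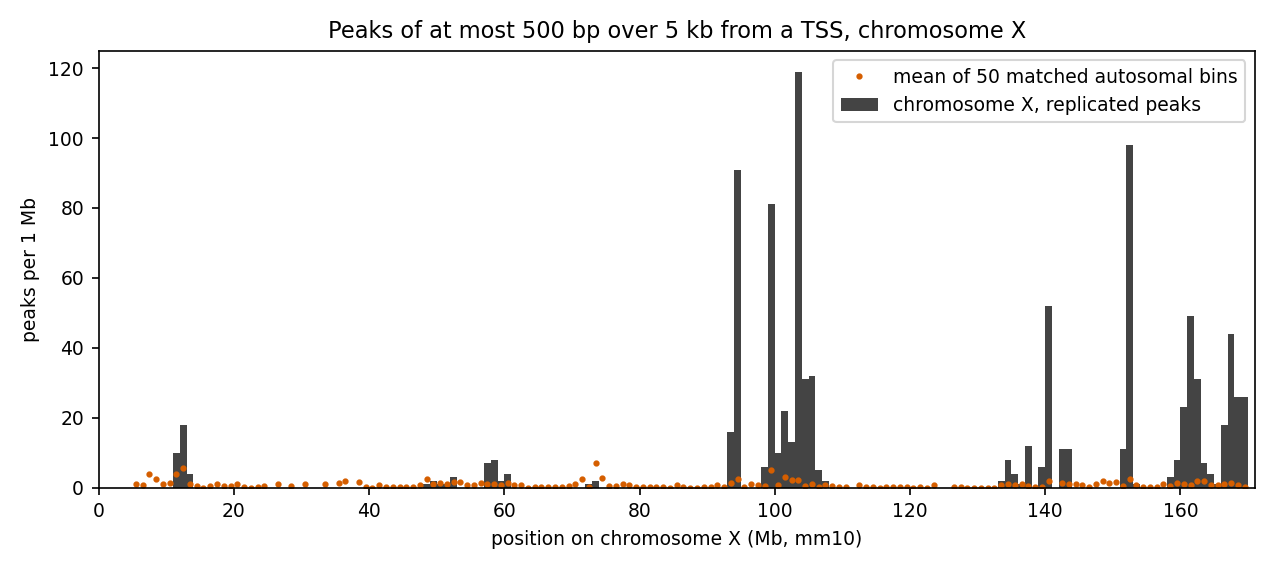
Replicated peaks of at most 500 bp over 5 kb from a protein-coding TSS, per 1 Mb bin of chromosome X (vertical axis, count; horizontal axis, mm10 position in Mb); black bars are X, and orange points the mean of 50 autosomal bins matched on GC content and gene number. The tallest bar, 119 peaks from 103 to 104 Mb, stands against a matched mean of 2.38.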

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

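The alternatives at −log10 q of at least 2 were chosen after the results were seen; all others were fixed before. Of 237 values of comparisons under alternatives, 216 were counted as kept and 1 as reversed. Tests counted as kept when direction and side of the threshold held, or when neither setting passed, whatever the direction. Blood cell genes, for example, were kept at 4.55% in replicate 2, below the 9.71% of all promoters marked there. Counts were kept within a factor of 1.5, CpG values within the replicate SD and signal agreement within a 95% interval across peaks. That SD came from the same 2 replicate lists that leaving out 1 replicate compares, so being kept there says little. The share marked in the fifth CpG decile, for example, counted as kept at 18.8% and 34.2% against 26.9%. Of 1760 values of 176 named genes, 1693 kept their marked or unmarked state. The reversal was chromosome X among promoters of CpG observed/expected of at least 0.6, at 17.4% marked; the cause was not tested, though this alternative leaves out CpG-poor promoters. At −log10 q of at least 5, marked promoters fell to 1545, replicate signal agreement to 0.148, lung mesenchyme to 13.8% and housekeeping stayed at 0% with its call lost. Housekeeping also lost its call with replicated peaks overlapping both replicates (0%), promoters of 500 bp (0%) or 2.5 kb (3.13%) either side and −log10 q of at least 2 (0%). Lung mesenchyme lost its call with peaks overlapping both replicates (17.2%), −log10 q of at least 2 (24.1%) and CpG-rich promoters only (42.9% of 7 genes), where imprinted genes lost theirs too (36.4% of 11 genes). Genes of differentiated cells of other organs gained a call with peaks overlapping both replicates (22.9%) and any transcript start (31.4%). Leaving out 1 replicate gave 17.2% to 44.8% for lung mesenchyme, 22.9% to 28.6% for differentiated cells of other organs, 0% to 0% for housekeeping, and a CpG rho of 0.127 to 0.128, which was 0.124 with CpG measured within 250 bp. The causes of these other changes were not tested. Of the 10 widest domains, 7 to 8 were recovered under each alternative. No paired analysis was possible because there was 1 group, so no samples of separate groups shared a number; contrasts within each replicate were not tested across the 2 replicates. Depth is unknown and limits what an absent peak in replicate 2 shows.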

Other observations

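The gene families, the start codon windows, the split of the Hox genes and bands of peaks on X, the test of auxiliary files and the test of single replicates in the Hox clusters were chosen only after results were seen. Gene symbols outside the lists were grouped by their shared letters, and 339 groups of at least 8 genes were tested by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment; 23 were marked more often than other genes and 6 less often. Those named here are examples. Others that passed were collagens (Col, 15 of 42), matrix metalloproteinases (Mmp, 9 of 22) and cadherins (Cdh, 9 of 21), with 21, 8 and 11 marked in replicate 1 and 9, 4 and 6 in replicate 2, while sodium channels (Scn, 6 of 14) did not pass (exact test, adjusted p = 0.0609). All 8 metabotropic glutamate receptors (Grm1 to Grm8) were marked in the replicated list and in both replicates (Fisher's exact test, adjusted p = 6.76e-06). Synaptotagmins, the calcium sensors of vesicle release, were marked at 15 of 17 genes (exact test, adjusted p = 8.65e-10), against 3.28 expected from their promoter CpG content, with 15 marked in replicate 1 and 10 in replicate 2. Serotonin receptors were marked at 10 of 14 genes (exact test, adjusted p = 5.97e-05).

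Among potassium channel families, Shaker-type Kcna genes were marked at 7 of 8 (Fisher's exact test, adjusted p = 1.79e-04), Kcnh genes at 7 of 8, inward rectifiers of the Kcnj family at 10 of 15 (adjusted p = 1.18e-04) and Kcnk genes at 9 of 14 (adjusted p = 3.97e-04). Subunits of voltage-gated calcium channels (Cacna) were marked at 9 of 14. In the other direction, 0 of 331 vomeronasal receptor genes (Vmn) and 14 of 394 Zfp zinc finger genes were marked, against 5.86 and 71.9 expected from CpG content; replicate 1 marked 25 of the Zfp genes and replicate 2 marked 11. Members of a family that lie side by side are not independent, so these p-values describe the lists in these samples.

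Replicate 2 had fewer peaks than replicate 1. Of the lung cell list promoters marked in replicate 1, 45.5% of 55 were lost in replicate 2, 4.77 percentage points over a mean of 40.7% (95% range 30.9% to 50.9%) in promoters of the same signal. The loss lay within 10 points of this mean, but the range is about as wide as that bound, so a different mix of lung cells in the pools stays open. Peaks of replicate 1 in the highest signal decile were found in replicate 2 15.3 times as often as those in the lowest (85.6% against 5.58%), but strong peaks would recur more often under any of these explanations, so weaker enrichment or lower depth in replicate 2 stays open. The extra auxiliary file behind the list of replicate 1 cannot be told apart from this for the ratio of 2.40 in peak number, since no call on equal files was among the files used.

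Chromosome X held bands of narrow peaks away from promoters. Counts per 1 Mb bin had a Spearman rho of 0.900 between the replicates over 154 bins, which argues against chance calls. Autosomes had a rho of 0.757 over 2376 bins, so such agreement was not particular to X. The median X bin held 0 in both replicates, and bins empty in both raise rho. X held 6.67 times as many such peaks as autosomal bins matched on GC content and gene number (6.16 per bin against 0.924, 95% range of matched draws 0.526 to 1.44). The draws treat neighbouring bins as independent, so this range may be too narrow for counts that form bands. They also mix bins of all autosomes, so the range leaves out the spread between chromosomes. No single autosome was compared in this way, so whether such an excess is particular to X was not tested. Without matching, autosomal bins held a mean of 2.63. The median X bin of the replicated list held 0, and 31 of all 154 bins (20.1%) exceeded the 95th percentile of their matches. This argues against GC content and gene number as the whole cause of the bands. Without the 16 densest bins the ratio was 1.70. The ratio was 5.22 in replicate 1 and 7.03 in replicate 2, which any cause particular to X would give. The inactive X of female cells, on which H3K27me3 is known to gather, therefore stays open, since mappability was not tested and peaks of male and female cells cannot be separated in pooled embryos.

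Genes of paralog groups 1 to 5 in the Hoxa and Hoxb clusters had less peak coverage than those of Hoxc and Hoxd, by 5362 bp around the start codon (10 against 5 genes). This split was drawn from the same data, so the difference is given without a p. CpG observed/expected around the start codon was higher by 0.133 in the Hoxa and Hoxb genes. This lay within the spread over genes (exact permutation test, two-sided, p = 0.294) and rested largely on Hoxd3, at 0.0806. The other Hoxc and Hoxd genes of these groups had 0.579 to 0.845, against a mean of 0.696 in Hoxa and Hoxb. Around the gene start the difference was -0.00437 (exact permutation test, p = 0.975), but this mean joins 2 unlike clusters. There the values were 0.624 to 0.996 in Hoxa and 0.181 to 0.790 in Hoxb, against 0.286 to 0.802 in Hoxc and Hoxd. The Hoxa range was thus not the lower one, while these ranges overlap and the genes are few. Lower CpG content therefore stays open, mainly for Hoxb. The difference did not come from 1 replicate, at 4219 bp in replicate 1 and 5518 bp in replicate 2. The design held no second tissue or stage, so no biological explanation was tested, and neighbouring genes share parts of their windows.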
